A study of Mus musculus with 2 samples.

How the data were processed

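RNA from mouse embryonic fibroblasts of 2 genotypes, wild type and TET1/TET2 knocked out, was sequenced with 1 library per genotype. Per the labels' protocols, RNA was taken from frozen cell pellets with TRIzol, treated with DNase and made into libraries with the TruSeq RNA v2 kit, which does not mark strand. The labels name the molecule as genomic DNA, although the protocol they give describes RNA. The submitters' processing notes name TopHat2 2.0, DESeq and the mouse build mm9. The counter, the annotation and the dispersion settings of DESeq are not given in the sources used here.

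The values come from a table of the authors' own comparison of a condition A with a condition B over 23365 genes. The signal is the authors' deposited mean over both conditions of gene counts divided by size factors, called the mean normalized count here. The authors' deposited ratio, or fold, is that of condition B over condition A. The authors' deposited log2 ratio equals the base-2 logarithm of that fold with no pseudocount, so a gene listed at 0 in 1 condition has an infinite ratio. Raw and adjusted p-values are the authors' own, from DESeq per the submitters' processing notes. The authors' adjusted p-values equal the Benjamini-Hochberg adjustment of their raw p-values over 17339 genes, and the other 6026 genes are listed at 0 in both conditions.

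The names of conditions A and B match the labels of neither sample. For this reason 2 columns of values, 1 for each condition, were set aside and not used in any form, and no ratio was assigned to a genotype. The comparison fixed before the data were examined was knock-out over wild type, and it became condition B over condition A. The planned pseudocount, counting intervals and the depth of each library would draw on the columns set aside, and they were not analysed here. No error is therefore given for single ratios. The targeted genes could not be checked against the labels, since the genotype of each condition is not given in the sources used here. With 1 library per genotype no test across samples was possible, and the authors' p-values compare 2 libraries, not the genotypes.

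Genes with a mean normalized count of at least 50 (12401 genes) were described by a size rule, a log2 ratio of at least 1 in size. Of these, 6 genes had an infinite ratio, 2 toward condition B and 4 toward condition A. Genes with an authors' adjusted p under 0.1, a cut-off set here, were counted and are termed the authors' calls. Before the data were examined, 44 gene lists with 1594 distinct entries were fixed, of which 10 entries matched no gene of the table. For lists with at least 5 members at the minimum mean, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins (seed 1). The percentile describes these libraries and is not a test of the genotypes. Adjustment over the list alone applied the Benjamini-Hochberg method to the authors' raw p-values of the list's members at the minimum mean, again under 0.1.

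The genes named were set by a rule fixed before the data were examined. It took Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b, Uhrf1 and Tdg. It took the 12 largest log2 ratios in each direction at the minimum mean, leaving out features with no gene symbol, ribosomal protein pseudogenes and predicted genes named Gm plus digits. It also took up to 4 members of each list with the largest ratios in size, the sex markers Xist, Ddx3y, Uty, Kdm5d and Eif2s3y, and further Hox genes at the minimum mean. Genes outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

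GC content and length were taken from the longest GENCODE M21 transcript of each symbol, and gene order from the RefSeq annotation of GRCm38, for 12339 and 12359 of the genes at the minimum mean. That build differs from the authors', so it was used for names, transcript properties and neighbours, and no coordinates are given. Alternatives were the trimmed mean of log2 ratios, with 30% of ratios and 5% of abundances trimmed at each end. Minimum means of 10, 200 and none were also used. Others were log2 ratios of at least 2 or 0.585 (1.5-fold) in size, an adjusted p under 0.05, and random lists not matched on expression. Centring on the median and removal of the trend on GC content and transcript length (20 bins each) were added after the data were seen. The size rule was tested on simulated data for condition B against condition A over 12401 genes, of which 200 were changed. The list percentile was tested on lists drawn at random from the deposited ratios. The trend removal was tested on those ratios shuffled among genes, with a simulated GC trend added. The size rule recovered 99.0% of genes simulated at a log2 ratio of 1.5 in size and 100% of those at 3, and 0 unchanged genes met it, with counting noise as the source of error. Of 100 random lists of 20 genes, 3 fell outside the central 95%, and of 100 such lists shifted by 0.7 on the log2 scale, 100 lay above it. The random lists came from the same ratios as those they were placed among, so few could fall outside. Smaller shifts and lists of other sizes were not tested. The members of these lists were drawn independently, so this does not cover lists of genes that vary together. The trend removal took a simulated rank correlation with GC content from 0.636 to 0.0024 over 12333 genes. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.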

Results

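Gene expression was measured by RNA sequencing in mouse embryonic fibroblasts, mesenchymal cells cultured from embryos, of 2 genotypes. Wild-type cells were compared with cells in which TET1 and TET2 had been knocked out, enzymes that oxidize 5-methylcytosine in DNA. Each genotype had 1 library. The series title names the question as how Tet1 and Tet2 bear on the regulation of developmental genes. The authors' deposited table compares a condition A with a condition B, and the genotype of each is not given in the sources used here. Every ratio is therefore stated as condition B over condition A, and none is assigned to the wild-type or knock-out cells. With 1 library per genotype, no difference has a replicate check. The authors' adjusted p-values come from DESeq on 1 library per condition and do not measure the spread between cultures. The depth of each library was not analysed here, and the mean normalized counts of the authors' deposited table sum to 58127871 over 23365 genes.

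Among 12401 genes with a mean normalized count of at least 50, the median log2 ratio was -0.04 and the quartiles were -0.39 and 0.30. In all, 2221 of these genes met the size rule, a log2 ratio of at least 1 in size. Of these, 1030 were higher in condition B and 1191 were higher in condition A. The authors' deposited table lists 397 genes at an adjusted p under 0.1, 246 of them higher in condition B and 151 higher in condition A. All 397 met the size rule, and the smallest log2 ratio in size among them was 1.97 in the authors' deposited table. These genes are said below to pass the authors' threshold, which means an adjusted p under 0.1 in the authors' deposited table. The cut-off of 0.1 and the adjustment over a list alone were set here.

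**Figure D1:**
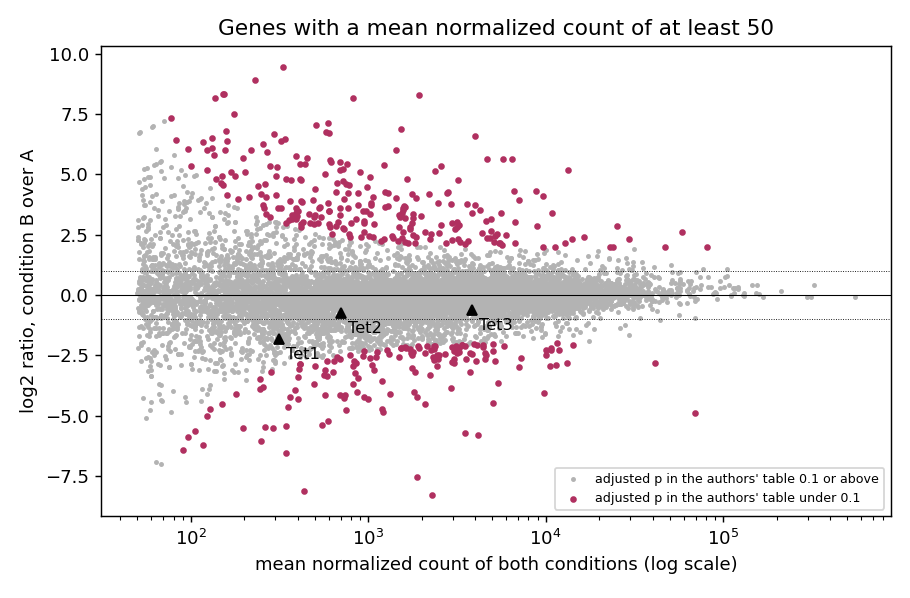
Each point is a gene with a mean normalized count of at least 50 (horizontal axis, log scale) and its log2 ratio of condition B over condition A in the authors' deposited table (vertical axis). Red points have an adjusted p under 0.1 there, dotted lines mark log2 ratios of -1 and 1, triangles mark Tet1 (-1.82), Tet2 (-0.74) and Tet3 (-0.63), and 6 genes listed at 0 in 1 condition are not drawn.

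The targeted genes were both lower in condition B. Tet1 was 3.54-fold lower in condition B in the authors' deposited table, with a mean normalized count of 313 and an adjusted p of 0.851. Tet2 was 1.67-fold lower in the authors' deposited table, with a mean normalized count of 704 and an adjusted p of 1. Tet3, the family member not targeted, was 1.55-fold lower in the authors' deposited table, also with an adjusted p of 1. The table gives 1 value per gene, so reads of a deleted exon could not be separated from the rest of the transcript, and these values do not show which condition is the knock-out. Of the 3 TET genes, 1 met the size rule and 0 passed the authors' threshold, also when adjusted over the list alone.

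The DNA methylation and demethylation machinery lay lower in condition B, with a median log2 ratio of -0.30 over 24 genes, at percentile 0.75 of random lists matched on expression. In this list 1 gene was higher in condition B and 7 were higher in condition A by the size rule. The authors' threshold was passed by 2 genes, both lower in condition B, and by 4, all lower in condition B, when adjusted over the list alone. Uhrf1, which guides maintenance methylation to newly replicated DNA, was 5.53-fold lower in condition B in the authors' deposited table (adjusted p = 0.0160). Apobec3, a cytidine deaminase, was 9.44-fold lower in the authors' deposited table (adjusted p = 0.00544). The maintenance methyltransferase Dnmt1 was 2.42-fold lower in the authors' deposited table (adjusted p = 0.713), and the de novo enzymes Dnmt3a and Dnmt3b had log2 ratios of -0.24 and -1.36 there, both with an adjusted p of 1. Hells, a chromatin remodeller needed for DNA methylation, had a log2 ratio of -1.71 and Cxxc4, among the 50 genes beside Tet2, one of 2.11 in the authors' deposited table, and neither passed. Tdg, the glycosylase that removes oxidized methylcytosine, is listed in the authors' deposited table at 0 in condition A, with a mean normalized count of 0.527. The annotation behind the counts is not given in the sources used here, so this value does not show whether Tdg was expressed. Uhrf1 also belongs to the DNA replication and S phase list, whose median log2 ratio was -1.49. The shift of the methylation list was not separated from that of replication genes.

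Among the largest ratios toward condition B, Serpina3h, a serine protease inhibitor, was 313-fold higher in condition B in the authors' deposited table, with a mean normalized count of 1936 (adjusted p = 1.28e-14). Prl3a1, a prolactin family hormone, was 289-fold higher in the authors' deposited table, with a mean of 825 (adjusted p = 5.51e-11). The interferon-induced Ifi27l2b and the GABA receptor subunit Gabra3 had log2 ratios of 9.44 and 8.92 in the authors' deposited table. Log2 ratios in the authors' deposited table were 8.35 for the cornified envelope gene Lce1g, 8.32 for the guanylate-binding protein gene Gbp1, 8.17 for Cyp4a12b, 7.53 for Serpinb6c and 7.34 for the mast cell protease gene Cma2. Serpinb7 had a log2 ratio of 7.22 in the authors' deposited table and did not pass (adjusted p = 0.105). Nkain3 and Lce1h are listed at 0 in condition A in the authors' deposited table, with mean normalized counts of 94.3 and 75.4, so no fold is given.

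Toward condition A, the largest ratio with values in both conditions was of Wnt10a, a secreted Wnt ligand, 310-fold lower in condition B in the authors' deposited table with a mean normalized count of 2298 (adjusted p = 8.39e-15). The epithelial keratin gene Krt7 was 186-fold lower in the authors' deposited table with a mean of 1875 (adjusted p = 6.35e-13). C4bp, of the complement system, had a log2 ratio of -6.53 in the authors' deposited table, Trim12a one of -6.41 and 1700030C10Rik one of -6.20. Fam189a1 (-7.01) and the endothelial gene Esm1 (-6.91) did not pass, with adjusted p-values of 0.138 and 0.176 in the authors' deposited table. Trim54, B3gnt3, Trim30d and Airn are listed at 0 in condition B in the authors' deposited table, with mean normalized counts of 122, 104, 95.3 and 70.7. Ratios of this size rest on a level near 0 in 1 condition, and no counting interval was computed for them. Values of Serpina3, Serpinb6, Lce1, Gbp, Cyp4a12, Ifi27l2, Trim12 and Trim30 genes are uncertain because these families hold near-identical copies, and Airn overlaps Igf2r in a library whose kit does not mark strand.

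Hox genes, which encode homeobox factors that mark position along the body axis and limb, differed by cluster. In Hoxc, 7 of 7 genes were higher in condition B by the size rule with a median log2 ratio of 5.11, and all 7 passed the authors' threshold, also when adjusted over the list alone. Hoxc8 was 40.3-fold higher in condition B in the authors' deposited table with a mean normalized count of 2587 (adjusted p = 1.20e-08). Hoxc13 had a log2 ratio of 6.39 in the authors' deposited table, Hoxc9 one of 5.70 and Hoxc10 one of 5.11, and Hoxc4, Hoxc5 and Hoxc6 lay at 3.90, 4.23 and 4.21. In Hoxb, 5 of 8 genes met the size rule, all higher in condition B, and 4 passed the authors' threshold, 5 when adjusted over the list alone. Hoxb6 was 11.1-fold and Hoxb9 10.3-fold higher in condition B in the authors' deposited table, and Hoxb7 and Hoxb8 had log2 ratios of 2.98 and 2.78. Hoxb5 did not pass, at 2.40, and their neighbours Hoxb2, Hoxb3 and Hoxb4 lay at 0.51, 0.53 and 0.28 in the authors' deposited table. In Hoxd, 8 of 8 genes were higher in condition B by the size rule, 1 of which passed the authors' threshold and 6 when adjusted over the list alone. Hoxd8, the gene that passed, was 8.82-fold higher in condition B in the authors' deposited table. The others were Hoxd3 at a log2 ratio of 3.46, Hoxd4 at 3.43, Hoxd9 at 2.15, Hoxd10 at 1.72, Hoxd11 at 2.87, Hoxd12 at 2.40 and Hoxd13 at 2.74 in the authors' deposited table. The medians of Hoxb (2.59) and Hoxc lay at percentile 100 and that of Hoxd (2.80) at percentile 99.98 of matched random lists.

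Hoxa genes went both ways, 3 of 9 higher in condition B and 4 higher in condition A by the size rule. Hoxa3 was 7.41-fold lower in condition B in the authors' deposited table (adjusted p = 0.0129) and was the Hoxa gene that passed. Hoxa2, Hoxa4 and Hoxa5 had log2 ratios of -2.18, -2.28 and -1.36 in the authors' deposited table, and Hoxa9, Hoxa10 and Hoxa11 had ratios of 2.12, 1.84 and 1.97. Hoxa7 lay at 0.30 in the authors' deposited table. When adjusted over the list alone, 3 were higher in condition B and 4 higher in condition A. The median was -0.58 at percentile 8, and it was 0.30 with a minimum mean of 10.

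**Figure D2:**
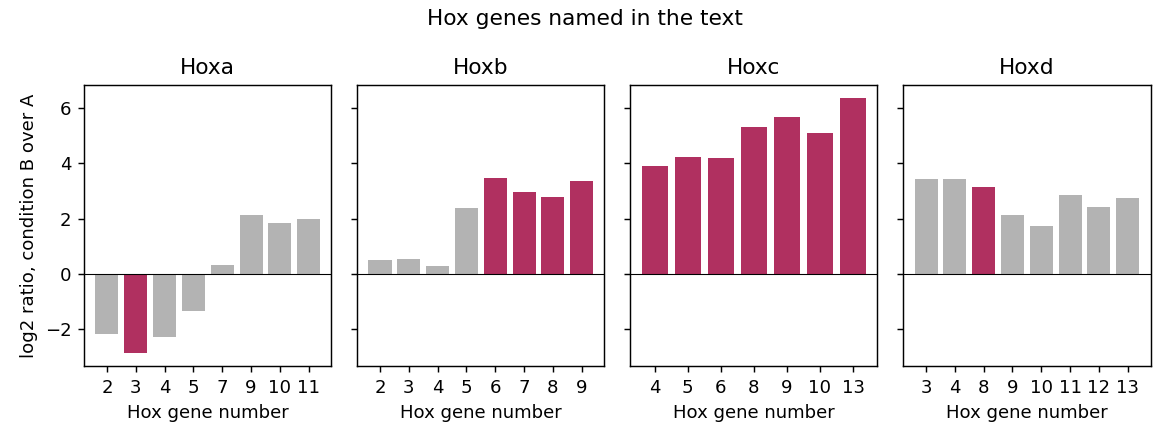
Bars give the log2 ratio of condition B over condition A in the authors' deposited table for the Hox genes named in the text, by cluster and gene number, and red bars have an adjusted p under 0.1 there. All 7 Hoxc bars are red and lie above 0, and Hoxa runs from -2.89 at Hoxa3 to 2.12 at Hoxa9.

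Genes of limb, axis and facial position went both ways with the larger share higher in condition B. By the size rule 11 of 22 were higher in condition B and 6 higher in condition A, with a median log2 ratio of 0.95 at percentile 100. Passing the authors' threshold were 4 and 3 genes, and when adjusted over the list alone 9 and 5. The homeobox genes Alx4 and En1, which pattern the limb and body wall, were 46.2-fold and 43.6-fold higher in condition B in the authors' deposited table. Pax1, a factor of the developing vertebral column, was 28.9-fold lower in the authors' deposited table with a mean normalized count of 1214 (adjusted p = 2.25e-06). Chosen after their values were seen, Pax9, Foxd1 and Nkx3-2 had log2 ratios of -4.30, -4.23 and -5.01 in the authors' deposited table and Tbx2 one of 4.80, and all 4 passed.

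Of 94 other developmental transcription factors, 30 were higher in condition B and 28 higher in condition A by the size rule. The authors' threshold was passed by 7 and 9, and by 14 and 19 when adjusted over the list alone, and the median of -0.03 lay at percentile 65.2. Sim2 was 52.2-fold lower in condition B in the authors' deposited table with a mean of 3534 (adjusted p = 5.23e-10). Its relative Sim1 had a log2 ratio of 6.98 in the authors' deposited table without passing (adjusted p = 0.195). Runx3, chosen after its values were seen, was 26.5-fold lower in condition B in the authors' deposited table.

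Cell division genes were lower in condition B. Of 46 genes of G2 and mitosis, 42 were lower in condition B by the size rule and 0 were higher, with a median log2 ratio of -1.87. Of these 46, 11 passed the authors' threshold and 42 did so when adjusted over the list alone. The proliferation marker Mki67 was 4.79-fold lower in condition B in the authors' deposited table with a mean normalized count of 10779 (adjusted p = 0.0298). The mitotic kinesin gene Kif11 was 5.09-fold lower, the kinetochore gene Cenpf 4.99-fold lower and the kinase gene Pbk 4.88-fold lower in the authors' deposited table. Of 41 genes of DNA replication and S phase, 34 were lower in condition B by the size rule and 0 were higher, with a median of -1.49. In this list 1 gene, Uhrf1, passed the authors' threshold, and 19 did so when adjusted over the list alone. The nuclease gene Exo1, the origin licensing gene Cdc6 and Mcm10 had log2 ratios of -2.21, -2.20 and -2.17 in the authors' deposited table and did not pass. Both medians lay at percentile 0 of matched random lists.

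Genes of the p53 response, growth arrest and senescence lay higher in condition B, with a median log2 ratio of 0.76 over 35 genes at percentile 100. By the size rule 10 were higher in condition B and 4 higher in condition A. The authors' threshold was passed by 2 and 1, and by 4 and 2 when adjusted over the list alone. Igfbp3, which binds insulin-like growth factors, had a log2 ratio of 4.32 in the authors' deposited table with a mean of 8830 (adjusted p = 6.84e-07). Cdkn2a, the locus of the cell cycle inhibitors p16 and p19Arf, was 3.98-fold higher in the authors' deposited table with a mean of 9644 (adjusted p = 0.0854). The inhibitor gene Cdkn1b was 5.30-fold lower in the authors' deposited table (adjusted p = 0.0252), and Rprm had a log2 ratio of 2.13 without passing. Cdkn1a and Mdm2, p53 targets chosen after their values were seen, had log2 ratios of 1.03 and 1.32 in the authors' deposited table and did not pass.

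Fibroblast and extracellular matrix genes lay higher in condition B. Of 75 genes, 27 were higher in condition B and 4 higher in condition A by the size rule, with a median log2 ratio of 0.48 at percentile 100. The authors' threshold was passed by 13, all higher in condition B, and by 20 higher and 3 lower when adjusted over the list alone. Dcn, the small proteoglycan decorin, was 50.5-fold higher in condition B in the authors' deposited table with a mean of 4688 (adjusted p = 3.60e-10). Tnxb (tenascin X) was 24.0-fold and Mfap4, of the microfibrils, 16.3-fold higher in the authors' deposited table, and the gelatinase gene Mmp9 had a log2 ratio of 4.06 without passing. Chosen after their values were seen, Thy1 and Pdgfra were 7.35-fold and 5.80-fold higher in condition B in the authors' deposited table, both passing. The collagen I genes Col1a1 and Col1a2, also chosen after their values were seen, had log2 ratios of -0.08 and -0.07 in the authors' deposited table at mean normalized counts of 312018 and 296200.

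Cartilage and bone genes lay lower in condition B, with 10 of 20 higher in condition A and 4 higher in condition B by the size rule and a median log2 ratio of -0.76 at percentile 0.02. The authors' threshold was passed by 4, all lower in condition B, and by 3 higher and 7 lower when adjusted over the list alone. Col2a1, the main collagen of cartilage, was 29.3-fold lower in condition B in the authors' deposited table with a mean normalized count of 69652 (adjusted p = 9.30e-09). The cartilage matrix gene Comp was 8.64-fold lower in the authors' deposited table (adjusted p = 0.0220). Acan, the proteoglycan aggrecan, had a log2 ratio of -3.08 and Bmp6 one of 3.62 in the authors' deposited table, and neither passed. Mgp and Sox9, chosen after their values were seen, had log2 ratios of -2.26 and -1.67 in the authors' deposited table, with adjusted p-values of 0.0287 and 0.315.

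Among contractile smooth muscle and myofibroblast genes, 5 of 23 were higher in condition B and 3 higher in condition A by the size rule, with a median of 0.33 at percentile 99.9. Passing the authors' threshold were 2 and 1 genes, and 3 and 1 when adjusted over the list alone. Smooth muscle myosin Myh11 was 8.03-fold and its kinase Mylk 5.53-fold higher in condition B in the authors' deposited table, and Csrp2 was 4.32-fold lower. Actg2 had a log2 ratio of 1.59 in the authors' deposited table without passing. Adipocyte genes were split, 3 of 20 higher in each condition by the size rule, with a median of -0.12 at percentile 27.6. Lipoprotein lipase Lpl was 12.5-fold higher and the lipid droplet gene Plin4 16.3-fold lower in condition B in the authors' deposited table, and these 2 were the genes that passed, also when adjusted over the list alone. Apoe (1.54) and Pparg (-1.40) did not pass in the authors' deposited table. Of 7 skeletal muscle genes, 2 were higher in condition B and 1 higher in condition A by the size rule, and 0 passed the authors' threshold, also when adjusted over the list alone. Their median was 0.47 at percentile 86.5, with log2 ratios of -3.70 for Tnni1, 1.88 for Tnnt2, 1.74 for Neb and 0.55 for Tnnc1 in the authors' deposited table.

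Markers of other cell types were also compared, since a fibroblast culture can hold other cells. Of 10 endothelial genes, 6 were higher in condition B and 2 higher in condition A by the size rule, 3 and 2 passed the authors' threshold, and 4 and 2 did so when adjusted over the list alone. The endothelial sialomucin gene Emcn, among the 50 genes beside Tet2, was 66.7-fold and Ecscr 27.4-fold higher in condition B in the authors' deposited table. There the endothelial transcription factor gene Erg was 49.0-fold lower. Emcn and Erg had mean normalized counts of 96.3 and 106, so their folds rest on a level near 0 in 1 condition. Kdr, a VEGF receptor gene, had a log2 ratio of 2.78 in the authors' deposited table and did not pass (adjusted p = 0.1001). The endothelial median was 1.36 at percentile 99.96, and 0.39 at percentile 92.3 with a minimum mean of 10. Of 7 mesothelial genes, 3 were higher in condition B and 2 higher in condition A by the size rule, 1 passed and, when adjusted over the list alone, 2 and 1. The uroplakin gene Upk1b was the gene that passed, 88.2-fold higher in condition B in the authors' deposited table. Aldh1a2 (4.93), Bnc1 (2.37) and Msln (-1.51) did not pass in the authors' deposited table. The mesothelial median was -0.02 at percentile 48.9, and 2.51 at percentile 100 with a minimum mean of 10.

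Of 14 epithelial and keratinocyte genes, 2 were higher in condition B and 4 higher in condition A by the size rule, with a median of 0.02 at percentile 64.7. Passing the authors' threshold were 2, both lower in condition B, and 1 higher and 3 lower when adjusted over the list alone. Besides Krt7, the desmosome gene Pkp1 was 19.2-fold lower in condition B in the authors' deposited table, and Sfn (-2.71) and Krt18 (-2.29) did not pass. Of 19 neural and glial genes, 7 were higher in condition B and 1 higher in condition A by the size rule, and 2 passed, both higher in condition B, also when adjusted over the list alone. These were the neurotrophin receptor gene Ngfr, 17.8-fold higher in the authors' deposited table, and the RNA-binding protein gene Elavl2, 12.4-fold higher. Chl1 (3.67) and Dner (1.52) did not pass in the authors' deposited table. The neural median was 0.21 at percentile 91.8, and 0.91 with a minimum mean of 10. Of 6 macrophage and leukocyte genes, 3 were higher in condition B, 1 was higher in condition A and 0 passed, also when adjusted over the list alone. Their median was 0.65 at percentile 81.6, with log2 ratios of 3.84 for Lyz2, -1.95 for Cd14, 1.79 for Cd53 and 1.05 for Csf1r in the authors' deposited table. The erythroid list had 1 gene at the minimum mean, and 0 of the list passed the authors' threshold, also when adjusted over the list alone.

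Of 8 sex-linked marker genes, 0 met the size rule and 0 passed the authors' threshold, also when adjusted over the list alone, and the median was -0.08 at percentile 30.4. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had log2 ratios of 0.44, 0.72, 0.10 and -0.26 in the authors' deposited table at mean normalized counts of 6683, 4322, 1740 and 2041. Xist, the RNA that coats the inactive X chromosome, had a mean of 2.06 in the authors' deposited table. The X-linked Kdm6a and Ddx3x had log2 ratios of -0.60 and -0.35 in the authors' deposited table.

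**Figure D3:**
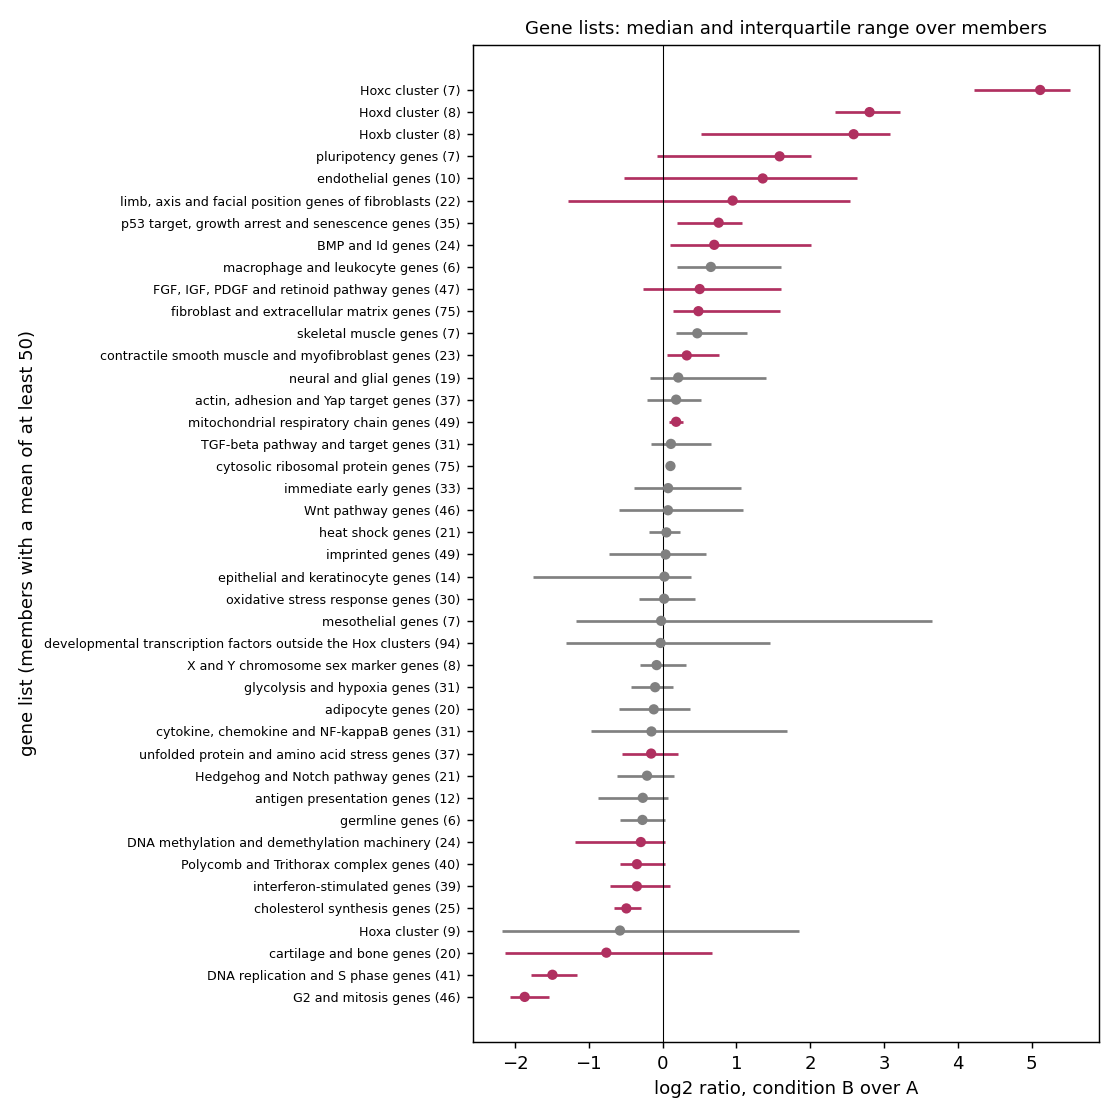
Points give the median log2 ratio of condition B over condition A over the members of each gene list with a mean normalized count of at least 50, whose number is in parentheses, and lines give the interquartile range. Red lists lie outside the central 95% of 10000 random lists matched on mean expression, 20 of 42 lists, with Hoxc (5.11) at the top and genes of G2 and mitosis (-1.87) at the bottom.

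Several signalling pathways held genes that were higher in condition B. Of 24 BMP and Id genes, 9 were higher in condition B and 0 higher in condition A by the size rule, with a median of 0.70 at percentile 100. The authors' threshold was passed by 5, all higher in condition B, and by 9 when adjusted over the list alone. The ligand genes Gdf6 and Gdf10 were 34.7-fold and 23.7-fold higher in condition B in the authors' deposited table. Of 31 TGF-beta pathway and target genes, 5 were higher in condition B and 4 higher in condition A by the size rule, 2 and 1 passed, and 3 and 2 did so when adjusted over the list alone. The BMP antagonist gene Nog was 7.12-fold higher and the matrix gene Tgfbi 7.52-fold lower in condition B in the authors' deposited table, and Cdkn2b had a log2 ratio of 1.87 without passing. The TGF-beta median was 0.11 at percentile 85.8.

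Of 47 genes of the FGF, IGF, PDGF and retinoid pathways, 19 were higher in condition B and 3 higher in condition A by the size rule, with a median of 0.50 at percentile 100. Passing the authors' threshold were 5 and 3 genes, and 9 and 3 when adjusted over the list alone. Crabp1, which binds retinoic acid, was 18.9-fold higher in condition B in the authors' deposited table, and Cyp26b1, which degrades retinoic acid, was 23.1-fold lower (adjusted p = 2.00e-06). Of 46 Wnt pathway genes, 13 were higher in condition B and 8 higher in condition A by the size rule, 6 and 3 passed, and 8 and 6 did so when adjusted over the list alone. The Wnt antagonist gene Dkk2, also among the 50 genes beside Tet2, was 95.5-fold higher in condition B in the authors' deposited table with a mean of 3984 (adjusted p = 2.49e-12), and the ligand genes Wnt4 and Wnt2 were 110-fold and 42.7-fold higher. The Wnt median was 0.07 at percentile 88.2. Of 21 Hedgehog and Notch genes, 5 were higher in condition B and 2 higher in condition A by the size rule, with a median of -0.21 at percentile 8.10. The Notch ligand gene Jag1, the gene that passed, was 5.50-fold higher in condition B in the authors' deposited table, and 2 higher and 1 lower passed when adjusted over the list alone. Hey1 (2.43), Hes1 (1.66) and the Hedgehog receptor gene Ptch1 (-1.88) did not pass in the authors' deposited table.

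Imprinted genes, which are expressed from the allele of a single parent, included large ratios both ways. Of 49, 5 were higher in condition B and 12 higher in condition A by the size rule, with a median of 0.04 at percentile 70.9. Passing the authors' threshold were 2 and 8 genes, and 3 and 9 when adjusted over the list alone. Impact was 55.4-fold lower in condition B in the authors' deposited table with a mean of 4164 (adjusted p = 2.60e-10), Gatm, of creatine synthesis, was 44.0-fold lower and Zdbf2 was 45.6-fold higher. Chosen after their values were seen, Asb4, Peg10, Slc38a4 and Plagl1 had log2 ratios of -4.02, -2.99, -2.41 and -2.11 in the authors' deposited table, all passing. Also chosen so, the growth factor gene Igf2 was 7.60-fold higher in condition B in the authors' deposited table (adjusted p = 0.00240), while its neighbour H19 and the receptor gene Igf2r had log2 ratios of 0.40 and 0.68 and did not pass.

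Polycomb and Trithorax genes, encoding chromatin regulators, lay lower in condition B, with a median of -0.35 over 40 genes at percentile 0.02. Their median was -0.19 after removal of the GC content and length trend. By the size rule 0 were higher in condition B and 3 higher in condition A, and 0 passed the authors' threshold, also when adjusted over the list alone. The histone methyltransferase gene Ezh2 had a log2 ratio of -1.63, Phf19 one of -2.12, Phc1 one of -1.43 and Cbx2 one of -0.87 in the authors' deposited table. Of 70 germline genes, 6 had the minimum mean, 1 of which was higher in condition A by the size rule and 0 of which passed, also when adjusted over the list alone. The germline median was -0.27 at percentile 35.8, and 0.77 with a minimum mean of 10. Syce2, Stag3, Tdrkh and Brdt had log2 ratios of -1.27, 0.77, -0.65 and -0.34 in the authors' deposited table. Of 7 pluripotency genes, 4 were higher in condition B and 2 higher in condition A by the size rule, and 0 passed, 3 higher in condition B when adjusted over the list alone. Their median was 1.58 at percentile 99.75, and 0.30 at percentile 78.4 with a minimum mean of 10. Klf4 had a log2 ratio of 1.67 at a mean of 12789, Lefty1 one of 3.01, Trim71 one of 2.35 and Tfcp2l1 one of -2.88 in the authors' deposited table.

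Interferon-stimulated genes of the list used here lay lower in condition B, with a median of -0.35 over 39 genes at percentile 1.29. The list holds neither the interferon-induced Ifi27l2b nor the guanylate-binding protein gene Gbp1. These had log2 ratios of 9.44 and 8.32 in the authors' deposited table. This list lay at percentile 7.45 with a minimum mean of 200 and 2.98 after removal of the GC content and length trend, inside the central 95%. By the size rule 3 were higher in condition B and 9 higher in condition A. The exonuclease gene Isg20 was the gene that passed, also when adjusted over the list alone, 7.29-fold lower in condition B in the authors' deposited table (adjusted p = 0.0866). Rtp4, H2-K1 and Mnda had log2 ratios of -1.58, -1.42 and -1.41 in the authors' deposited table without passing. Of 12 antigen presentation genes, 1 was higher in condition B, 3 were higher in condition A and 0 passed, also when adjusted over the list alone, and the median was -0.27 at percentile 15.1. Nlrc5 (-3.13), Psmb8 (-1.38) and Tap1 (1.05) met the size rule in the authors' deposited table. Cytokine, chemokine and NF-kappaB genes went both ways, 10 of 31 higher in condition B and 8 higher in condition A by the size rule, with 7 and 3 passing and 8 and 6 when adjusted over the list alone. The chemokine genes Ccl20 and Ccl2 were 34.8-fold and 8.15-fold higher in condition B in the authors' deposited table, the adhesion receptor gene Icam1 was 16.5-fold higher and the membrane-bound chemokine gene Cx3cl1 was 12.6-fold lower. The median of this list was -0.15 at percentile 10.6.

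Cholesterol synthesis genes lay lower in condition B, with a median of -0.49 over 25 genes at percentile 0, 23 of them below 0. In that list 0 were higher in condition B and 1 was higher in condition A by the size rule, and 0 passed, also when adjusted over the list alone. Stard4, Lss and Pmvk had log2 ratios of -0.95, -0.85 and -0.84 in the authors' deposited table. Of 31 glycolysis and hypoxia genes, 0 were higher in condition B, 2 were higher in condition A and 0 passed, also when adjusted over the list alone, with a median of -0.10 at percentile 6.03. Car9, Aldoc, Egln3 and Ndrg1 had log2 ratios of -1.68, -1.02, 0.95 and -0.89 in the authors' deposited table. Unfolded protein and amino acid stress genes had a median of -0.16 over 37 genes at percentile 0.74, or 11.35 of random lists not matched on expression, with 1 higher in condition B and 5 higher in condition A by the size rule. The cystine transporter gene Slc7a11 was the gene of this list that passed, also when adjusted over the list alone, 6.49-fold lower in condition B in the authors' deposited table (adjusted p = 0.00940). Cth (-1.62), Psat1 (-1.23) and Trib3 (-1.16) did not pass in the authors' deposited table. Of 30 oxidative stress response genes, 4 were higher in condition B and 1 higher in condition A by the size rule, with a median of 0.02 at percentile 62.7. Gsta4, a glutathione transferase gene, was 9.74-fold higher in condition B in the authors' deposited table, and with Slc7a11 it passed, also when adjusted over the list alone. Cbr3 (1.43) and Gstm2 (1.12) did not pass in the authors' deposited table.

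Of 33 immediate early genes, 9 were higher in condition B and 5 higher in condition A by the size rule, with a median of 0.07 at percentile 79.95. The transcription factor genes Fosb and Fos, the 2 that passed, were 8.17-fold and 3.997-fold higher in condition B in the authors' deposited table, and 4 higher and 2 lower passed when adjusted over the list alone. Dusp2 (-4.83) and Arc (-2.13) did not pass in the authors' deposited table. Of 21 heat shock genes, 2 were higher in condition B by the size rule and 0 passed, also when adjusted over the list alone, with a median of 0.05 at percentile 56.4. Hspa1b, Hspa1a, Dnajb4 and Bag3 had log2 ratios of 1.43, 1.30, 0.69 and 0.54 in the authors' deposited table, and reads of the near-identical Hspa1a and Hspa1b are hard to separate. Of 37 actin, adhesion and Yap target genes, 4 were higher in each condition by the size rule, with a median of 0.18 at percentile 94.0. The integrin genes Itga4 and Itga2 were 8.51-fold and 8.14-fold higher and Itga3 4.93-fold lower in condition B in the authors' deposited table, and these 3 passed, also when adjusted over the list alone, while Itgb8 (-2.37) did not.

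Of 75 cytosolic ribosomal protein genes, 0 met the size rule and 0 passed, also when adjusted over the list alone, and the median was 0.11 at percentile 59.1. It lay at percentile 98.25 of random lists not matched on expression, and after removal of the GC content and length trend the median was 0.02 at percentile 0.925. Rps27, Rplp1, Fau and Rps21 had log2 ratios of 0.41, 0.30, 0.29 and 0.25 in the authors' deposited table. Of 49 mitochondrial respiratory chain genes, 0 met the size rule and 0 passed, also when adjusted over the list alone, and the median of 0.18 lay at percentile 99.8, or 92.6 after removal of the GC content and length trend. Cox6a1, Cox8a, Cox4i1 and Cox6b1 had log2 ratios of 0.57, 0.50, 0.50 and 0.44 in the authors' deposited table.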

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

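Centring on the median log2 ratio and removal of the GC content and transcript length trend were chosen after the data were seen, and the other alternatives before. The size rule gave 3161 genes higher in condition B and 2336 higher in condition A with no minimum mean, 476 and 366 at a size of 2, and 1727 and 2160 at a size of 1.5-fold, against 1030 and 1191, since these settings by construction test more genes or ask for another size. Counts stayed within 1.5 times for the trimmed mean (1074 and 1140), centring on the median (1069 and 1144) and minimum means of 10 (1521 and 1480) and 200 (695 and 922). The authors' calls numbered 200 and 101 at an adjusted p under 0.05, against 246 and 151. Between 19 and 24 gene lists lay outside the central 95% under the alternatives, against 20 of 42, and these were not always the same lists. The 19 were among the 36 lists with enough members at a minimum mean of 200. Centring shifts a list and its random lists alike. The counts of 20 under the trimmed mean and the median were therefore fixed but for random draws. The pluripotency and endothelial lists left and the mesothelial and neural lists entered at the high end with a minimum mean of 10. With a minimum mean of 200, the interferon list left and the Hoxa and other developmental factor lists entered at the low end. At that minimum 6 lists had too few members. Among them were the Hoxd and pluripotency lists, which lay outside the central 95% in the main setting. Against random lists not matched on expression, the unfolded protein list left and the skeletal muscle, leukocyte, ribosomal protein and actin lists entered at the high end and the Hoxa list at the low end. After removal of the GC content and length trend, the interferon and respiratory chain lists left and the neural and TGF-beta lists entered at the high end and the cytokine and ribosomal protein lists at the low end. The cause of these changes was not tested. Of 246 list medians under an alternative, 240 moved by less than 1.5-fold and 6 moved further, all with a minimum mean of 10, where more low genes enter. The 42 medians set against random lists not matched on expression could not move, since only the random lists differ there. Centring on the trimmed mean or the median shifted every list by the same 0.04, so those medians could not move by 1.5-fold either. Scaling to the total, scaling by the upper quartile and the planned pseudocounts were not run, since they draw on the columns per condition that were set aside because their names match no sample's labels. No paired analysis was possible because each genotype had 1 library. Depth per library was not analysed here, so no counting error is given for low genes.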

Other observations

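Centring on the trimmed mean was planned as an alternative, and its use as a test of scaling, the other tests below and the gene families named here were chosen after the data were seen. For GC content and length and for the genes beside Tet1 and Tet2, what each outcome would mean was set before its value was seen. Of the small proline-rich genes at the minimum mean, Sprr2k had a log2 ratio of 6.02 (adjusted p = 0.000855) and Sprr3 one of 3.75 without passing in the authors' deposited table, beside the cornified envelope genes Lce1g and Lce1h. Of 4 Serpina3 genes, 3 were higher in condition B by the size rule and 2 passed the authors' threshold. Serpina3i had a log2 ratio of 6.02 and Serpina3g one of 2.11 in the authors' deposited table, and Serpina3n one of 0.19.

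Of 5 Gbp genes, 2 were higher in condition B by the size rule and Gbp1 passed, while Gbp2, Gbp3 and Gbp7 had log2 ratios of -0.51, -0.24 and -0.35 and Gbp9 one of 2.94 in the authors' deposited table. Trim12c had a log2 ratio of 0.85 in the authors' deposited table against -6.41 for Trim12a, and Ifi27l1 one of 1.51 against 9.44 for Ifi27l2b. Ratios of such copies are uncertain, since the authors' counting could divide their reads.

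Hoxb, Hoxc and Hoxd genes were higher in condition B, with a median log2 ratio of 3.14 over 23 genes. Removing the trend on GC content and transcript length left a median of 3.06, which argues against that bias as the whole cause. Cultures from different body positions are a candidate explanation. Gene number and log2 ratio, both centred within cluster, had a Spearman correlation of 0.593 across 32 Hox genes (permutation p = 0.00068 within clusters, two-sided). Without centring it was 0.389, and by cluster it was 0.733 in Hoxa, 0.762 in Hoxb and 0.857 in Hoxc. What this correlation would mean was set after the data were seen, and genes are not independent replicates, so its p-value does not test body position. In Hoxd alone the correlation was -0.619 over 8 genes (exact permutation p = 0.115, two-sided), which decides neither way. In none of the clusters can body position be told apart from the genotype, since any difference in position would lie between the genotypes. The knock-out, which the design names, stays open and untested, since each genotype had 1 library.

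Genes of replication and mitosis were lower in condition B, 76 of 87 by the size rule and 1 of 87 above 0. Their median was -1.68 and was -1.63 after removal of the GC content and length trend, which argues against that bias as the whole cause. Centring on the trimmed mean of all genes gave -1.64, but it moves every gene alike. The scaling between the conditions therefore stays open as a source of the absolute level. Such scaling cannot explain why the replication and mitosis medians lay at percentile 0 of matched random lists, which it moves by the same amount. Growth state at harvest, such as passage or density, might differ between the libraries. Genes of the p53 response, growth arrest and senescence had a median log2 ratio of 0.76. By the size rule 10 of them were higher in condition B and 4 higher in condition A. These values bear on growth state but do not separate it from the genotype. The genotype also stays open and untested.

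DNA carried over from embryonic stem cells beside a targeted locus may differ by strain from the rest of the genome. Of the 50 genes at the minimum mean beside Tet2, 17 met the size rule, at percentile 98.2 of windows along the genome, whose median was 9. The 50 genes beside Tet1 held 14, at percentile 92.4, which leaves that locus undecided. The 17 genes include Dkk2, Emcn and Cxxc4 and, named after their values were seen, Adh1 and Adh7 of a single family and the cell division gene Cenpe, so they are not independent. Strain is not given in the sources used here, so this remains a hypothesis beside chance and the genotype itself.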
